A study of Homo sapiens with 18 samples.

How the data were processed

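A549 cells, a human lung adenocarcinoma line, were profiled by CUT&Tag, in which an antibody bound to chromatin directs a transposase that inserts sequencing adapters nearby. The series holds 18 samples. Wild-type cells (WT), YTHDF1-knockout cells (YTHDF1-KO) and cells with ARID1A knocked down by siRNA (siARID1A) were each profiled with an antibody against YTHDF1, an antibody against ARID1A and normal IgG, with 2 replicates each. Peak lists of the 12 anti-YTHDF1 and anti-ARID1A samples were analysed. The 6 IgG samples and the combined knockout and knockdown condition that the design text names were not analysed here. Groups and replicate numbers were taken from the sample titles. The labels do not state whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

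Each list was made per sample. Per the submitters' processing notes, fastp 0.23.2, Bowtie2 2.4.2, SAMtools 1.9, bedtools 2.30.0, SEACR 1.3 and deepTools 3.5.2 were used with the builds hg38 and GRCh38. Settings and the role of IgG in peak calling are not given in the sources used here. The deposited lists have 6 columns: a position, the total signal of the peak, its highest signal and the place of the highest signal. Both signal columns hold coverage on a scale the authors set for each library. In every list 100% of the highest values were whole multiples of a single step, within 0.01 of a step or 0.01% of the value. The steps lay close to 10000 divided by a whole number between 85 and 31102. What the number refers to is not given in the sources used here, so signal was not compared between libraries as a level. The authors' signal per peak was used to describe, rank or filter peaks within a list, and, after each library was centred on its own median, which removes any constant of the library, to compare parts of the genome with one another. Shares of signal within a list are likewise free of its scale. The sequencing depth of the libraries is unknown, and no interval that needs it is given.

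Peaks on chromosomes 1 to 22 and X were used. Peaks elsewhere made up 3.57% to 6.65% of a list, and each list held 1 peak covering the mitochondrial genome. No peaks of a list overlapped one another, and no pair of lists was identical. For each comparison of a condition with WT, the peaks of the 4 libraries were merged into regions, and a library held a region if any of its peaks overlapped it by 1 bp or more. Regions held by both libraries of one condition and by neither of the other were counted in both directions. The count was set beside those of the 2 other ways to split the 4 libraries into pairs. With 2 libraries against 2 no test per region or gene was made, and the smallest p-value that an exact two-sided permutation test can give is 0.33.

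Gene positions came from a RefSeq gene table of GRCh38.p14, which gives no strand, so promoters could not be placed. In their stead, a gene counted as held by a library if a peak overlapped a window of 1 kb to either side of either annotated end. This differs from the design set before the data were examined, which named gene starts. A window can hold the 3' end of a gene or the promoter of a neighbour, and overlapping or adjacent genes can share a peak. The table had 19974 protein-coding genes on these chromosomes. A few of its positions may belong to alternate sequences rather than to the chromosome named. Genomic sequence was not used here, and the planned motif comparison was not run. Coordinates are 1-based GRCh38 positions.

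The tests, the gene lists and the naming rules were fixed before the data were examined unless said otherwise. For each comparison and direction the rules took the members of fixed gene lists, at most the 15 with the highest mean percentile of total signal within their libraries, and the 8 genes of highest mean percentile. The zinc finger and olfactory receptor lists were left out of the first rule. YTHDF1 and ARID1A were followed in every library, and 3 regions per comparison and direction were taken by percentile. The 21 lists covered R-loop resolution, nucleic acid sensing, interferon-stimulated genes, antigen presentation, immune checkpoint ligands, cytokines and chemokines, SWI/SNF subunits, m6A machinery, DNA damage response, p53 targets, NRF2 targets, the AP-1 and ATF family, lung epithelium, EMT, cell cycle, haematopoietic and neuronal markers, ribosomal proteins, replication-dependent histones, zinc finger genes and olfactory receptors. List members were compared with the other genes that could have shown the pattern by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 168 tests and a threshold of 0.05. The genes that could have were those held by both WT libraries for a pattern of loss, and those held by neither for a pattern of gain.

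The antibodies were compared over all 12 libraries, 6 against 6. Fisher's exact test per gene, two-sided, was adjusted by the Benjamini-Hochberg method over the genes held by at least 1 library. The share of peaks at gene ends and the share of each list's members with a peak were tested by exact two-sided permutation over 924 assignments. Shuffled positions for co-occupancy were drawn 100 times within chromosomes. Chromosome shares of peaks were compared between cell stocks with all 12 libraries, after taking log2 and centring on the mean of the antibody, by exact permutation of 4 libraries against 8 with adjustment over 69 tests. This test was chosen after the shares had been seen. Signal shifts between cell stocks were taken as the median log2 difference over regions held by all 4 libraries, per chromosome and per 20 Mb window with at least 20 regions.

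The gene list tests at equal length, the comparison of gene ends with other regions matched on WT signal in 10 groups each by total and highest signal, the gene classes, for which a peak over any part of a gene or the 1 kb to either side counted, the segment bounds on chromosomes 9 and 17, the genes named from the antibody comparison, the olfactory receptors named beside their counts and BATF in siARID1A cells were chosen after seeing the data.

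The counting code was tested on simulated data. All 200 regions planted in each direction among 28882 were found in the 2 against 2 comparison, with 0 others. In the antibody comparison 100% of 500 genes per direction were found among 16791 tested when they were held by all 6 libraries of one antibody and none of the other. With 200 such genes per direction 0 were found, since the smallest p of 6 against 6 libraries passes the adjustment only where many genes reach it. Alternatives were gene windows of 500 bp and 3 kb, the upper 50% of each list by signal, lists cut to the length of the shortest, 1 kb bins, an overlap of 50% of the shorter interval, merging of peaks less than 1 kb apart, covered length, a replicate block, and leaving out each library. Gene lists with 3 kb windows or without chromosomes 2, 9 and 17 were also added after seeing the data, as were the top 20000 peaks of each list, the omission of chromosomes 2, 9 and 17, and windows covering the whole gene with 1 kb around it. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.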

Results

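The series profiles the chromatin of A549 lung adenocarcinoma cells with antibodies against 2 proteins. YTHDF1 is a reader of N6-methyladenosine in RNA, known mainly from the cytoplasm, and ARID1A is a subunit of a SWI/SNF chromatin remodelling complex. Peak lists were compared for WT, YTHDF1-KO and siARID1A cells, with 2 libraries per antibody and condition. The anti-YTHDF1 lists held 40562 to 59632 peaks on chromosomes 1 to 22 and X. The anti-ARID1A lists held 71271 to 106882. Anti-YTHDF1 peaks covered 69.5 ± 28.4 Mb in WT, 59.4 ± 2.25 Mb in YTHDF1-KO and 79.6 ± 2.94 Mb in siARID1A cells (mean ± SD, n = 2). Anti-ARID1A peaks covered 247 ± 27.2, 237 ± 5.05 and 113 ± 20.3 Mb in the same order. The sequencing depth behind these lists is unknown. In each comparison with WT an exact two-sided permutation test of 2 libraries against 2 cannot give a p below 0.33, so patterns at single genes are given as calls in both libraries of one condition and neither of the other.

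**Figure D1:**
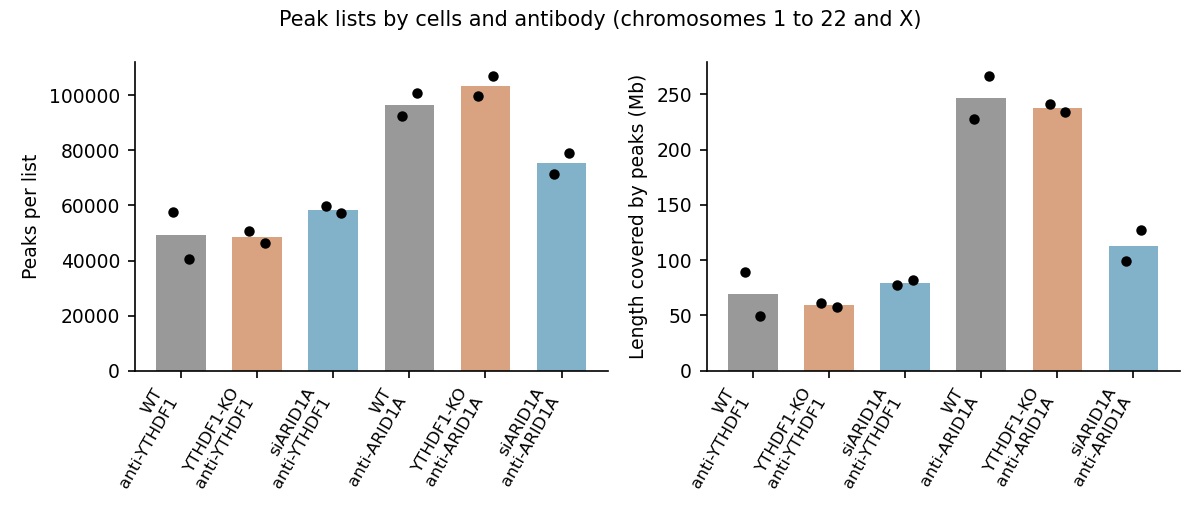
Number of peaks per list (left panel) and length they cover (right panel, in Mb) on chromosomes 1 to 22 and X, with a bar for the mean and a point for each of the 2 libraries of each antibody and cell condition. The siARID1A anti-ARID1A lists, at 71271 and 79193 peaks, were the shortest of the 6 anti-ARID1A lists.

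Anti-YTHDF1 lists were compared between WT and YTHDF1-KO cells. Pairings that mix WT and knockout libraries gave nearly as many gene ends as the real pairing (936 and 924 against 983). The genes named below are therefore not shown to depend on YTHDF1. An end of the YTHDF1 gene itself (chromosome 20, 63195429 to 63216131) carried a peak in all 12 lists, those of the knockout cells included. Peaks called in both WT and neither YTHDF1-KO library lay at an end of JUND, an AP-1 transcription factor, of MCM3, a subunit of the replicative helicase, and of CCNE2, a cyclin of S-phase entry. The same pattern was seen at YTHDF2 and IGF2BP2, which encode readers of N6-methyladenosine, at the RNA helicase DDX1 and the exoribonuclease XRN2 of the R-loop list, and at ADAR, an RNA-editing enzyme. Called in both YTHDF1-KO and neither WT library were ends of SMARCC2, a SWI/SNF core subunit, BATF, an AP-1 family member, NKG7, a granule protein of cytotoxic lymphocytes, RBFOX3, a neuronal splicing factor, CHAT, which makes acetylcholine, and the linker histone gene H1-2. With gene windows of 3 kb 12 of the 36 named genes of this comparison kept their pattern, MCM3, CCNE2, YTHDF2, DDX1, XRN2, BATF, CHAT and H1-2 among them, while JUND, IGF2BP2, ADAR, SMARCC2, NKG7 and RBFOX3 did not. Nor did the 8 WT genes of highest percentile, NPDC1 and SIRT3 among them, or SUN1, KLF1, CSF2 and TNFRSF14. DDX1 lies on chromosome 2 and RBFOX3 on the far part of chromosome 17, which differ between the cell conditions as a whole.

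JUND (chromosome 19, 18279694 to 18281622) stood at the 74.8 and 89.3 percentiles of the authors' total signal within the WT lists. MCM3 stood at 45.6 and 75.2, and YTHDF2, a weak peak, at 14 and 15.3. Among the genes of highest percentile in WT were NPDC1 (99.7 and 97.1), which lies in the part of chromosome 9 that differs between the cell conditions, and SIRT3, a mitochondrial deacetylase (97.2 and 93.8). FAM72A and CASTOR2 were also among them but have near-identical copies, so their assignment is uncertain. In the knockout lists SUN1, a nuclear envelope protein, stood at 86.2 and 93.4. Further WT-only list members were PVR and TNFRSF14, which bind receptors of lymphocytes, the erythroid factor KLF1, the growth factor gene CSF2 and RPS13. The strongest WT-only regions lay in NKD2 on chromosome 5 (1022907 to 1026349) and over GZMM on chromosome 19 (547329 to 553327). The strongest knockout-only region lay in DOCK8 on chromosome 9 (320141 to 322467).

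Gene ends called in both WT and neither YTHDF1-KO library numbered 700, against 283 in the opposite direction. Among merged regions the counts were 3588 and 2254, while 8120 regions were held by all 4 libraries. The 2 other ways of pairing these libraries gave sums of 5867 and 5626 regions, against 5842 for the real pairing, and 936 and 924 gene ends against 983. These mixed pairings were uneven as well, with 713 against 223 and 636 against 288 gene ends. Their regions numbered 4365 against 1502 and 4051 against 1575. With lists cut to equal length WT-only and knockout-only regions numbered 3076 and 1953, and the mixed pairings gave 2688 against 1723 and 2934 against 1636. The excess of WT-only over knockout-only calls is therefore not shown to come from the knockout. Peak numbers stood at a ratio of 1.00 between knockout and WT (exact permutation p = 1, n = 2 each). The WT lists themselves held 57764 and 40562 peaks, and the ratio ranged from 0.839 to 1.19 when single lists were left out. A peak of one WT list overlapped the other WT list in 42.0% of cases on average, and a YTHDF1-KO list in 37.1%. A peak of one YTHDF1-KO list overlapped the other in 35.7%, and a WT list in 39.3%. Of the 21 gene lists only the olfactory receptors differed from other genes, with 1 of 375 members (OR4D1) called in the knockout alone, against 3.42% of other genes (Fisher's exact test, adjusted p = 0.00469). Olfactory receptors seldom carried a peak with either antibody (2.56% of them with anti-YTHDF1 and 4.15% with anti-ARID1A). Few calls were therefore likely in any pairing, and the result is not tied to the knockout.

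**Figure D2:**
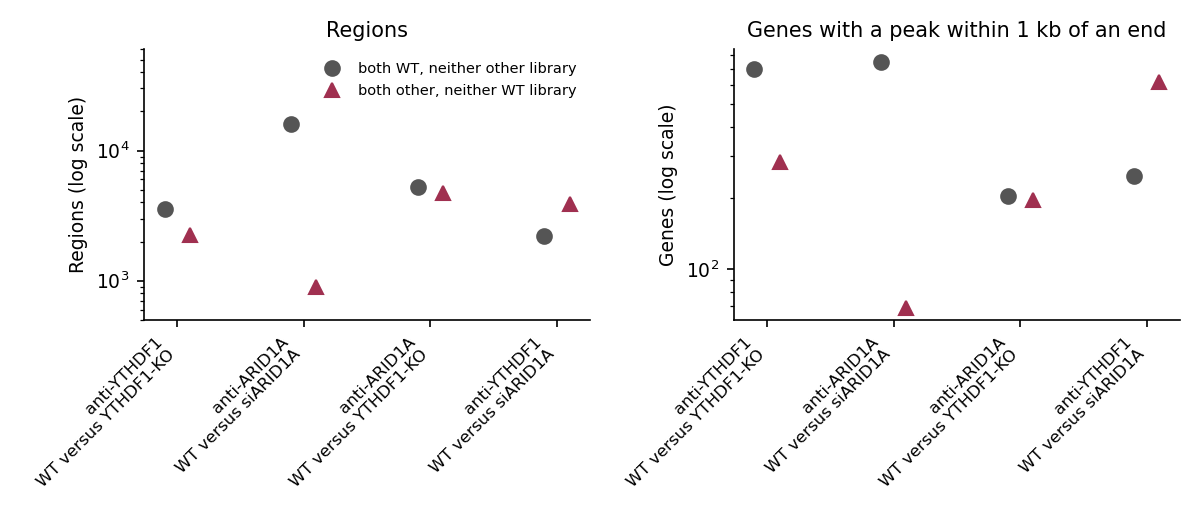
Regions (left) and genes with a peak within 1 kb of an end (right), both on a log axis, that were called in both WT and neither other library (circles) or the reverse (triangles) in the 4 comparisons with WT. The directions lie farthest apart for anti-ARID1A in siARID1A cells, at 15950 and 897 regions and 754 and 69 genes.

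Anti-ARID1A lists of siARID1A cells held fewer regions than those of WT cells. Called in both WT and neither siARID1A library were ends of TWIST2, a transcription factor of mesenchymal cells, THOC2 of the mRNA export machinery, RNASEH2B, a subunit of the enzyme that removes RNA from RNA-DNA hybrids, and the SWI/SNF subunit genes PHF10 and BRD7. Also in this class were the DNA sensor gene IFI16, the aldo-keto reductase gene AKR1C3, the surfactant gene SFTPA2, the co-stimulatory ligand gene CD80, the N6-methyladenosine writer subunit gene ZC3H13, the T-cell receptor subunit gene CD3E and the histone genes H3C12 and H2BC9. With gene windows of 3 kb 11 of the 29 named genes of this comparison kept their pattern, RNASEH2B, IFI16, SFTPA2, CD80, ZC3H13 and CD3E among them, while TWIST2, THOC2, PHF10, BRD7, AKR1C3, H3C12, H2BC9 and the 8 WT genes of highest percentile did not. Neither did COLGALT2, TAF11L8 and FOXI3, which were called in siARID1A alone. In the opposite direction 69 genes were called, and none belonged to a fixed list other than 2 zinc finger genes. The ARID1A gene (chromosome 1, 26696015 to 26782104) carried a peak at an end in all 6 anti-ARID1A lists, siARID1A included.

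TWIST2 (chromosome 2, 238848085 to 238910534) stood at the 85.3 and 93.8 percentiles of total signal in the WT lists, THOC2 at 71.7 and 55.9 and PHF10 at 70.7 and 48.4. The genes of highest percentile in WT were PNPLA5, FYB1, SEPTIN12, PFKFB2, GARRE1, LAMC3, SPDYE2B and GSE1. PFKFB2, an enzyme that controls glycolytic flux, stood at 95.6 and 96.7. LAMC3, a laminin chain whose gene lies in the shifted part of chromosome 9, stood at 94.1 and 97.7. SPDYE2B has near-identical copies and is uncertain. Called in siARID1A alone were ZNF800 (71.3 and 61.5), the integrin gene ITGA4 (72.7 and 54.9), COLGALT2, ADAMTS19, SNRK, TXNDC5 and FOXI3, besides TAF11L8, which has copies. The strongest WT-only regions lay in TACC2 on chromosome 10 (122180111 to 122188352) and in TMC1 and MAPKAP1 on chromosome 9, the latter in its shifted part.

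Gene ends of WT alone numbered 754, against 69 for siARID1A alone, and regions 15950 against 897. The sum of 16847 regions compares with 5336 and 4705 for the other pairings, and 823 gene ends with 299 and 277. Peak numbers stood at a ratio of 0.779 (exact permutation p = 0.33, the smallest possible, n = 2 each), with both siARID1A lists shorter than both WT lists, and covered length at a ratio of 0.456. Of the gene ends held by both WT libraries 5.42% were called in neither siARID1A library, and no gene list differed from other genes after adjustment. Of the members held in WT these were 2 of 22 for R-loop resolution, 2 of 21 for SWI/SNF subunits, 1 of 20 for N6-methyladenosine machinery and 1 of 17 for nucleic acid sensing. With lists cut to equal length WT-only regions numbered 9298 and siARID1A-only regions 1335, and 0 of 377 olfactory receptors were called in siARID1A alone (Fisher's exact test, adjusted p = 0.00230), a test chosen after seeing the data, of a list that had not passed with all peaks. Olfactory receptors seldom carried a peak with either antibody, so this is not tied to the knockdown. In these cells 47.2 ± 3.23% of the listed signal lay on the mitochondrial chromosome, against 18.7 ± 0.885% in WT (n = 2 each), beside covered lengths of 113 ± 20.3 and 247 ± 27.2 Mb.

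The anti-ARID1A lists of YTHDF1-KO cells were compared with those of WT cells. Called in both WT and neither knockout library were ends of BRD7 and H3C12, which also showed the pattern in siARID1A cells, of RPL29, of NEUROD1, a neuronal transcription factor, and of IL1A, an inflammatory cytokine. Called in both knockout and neither WT library were SPARC, a matrix protein gene, DDX39B, an RNA helicase of mRNA export, NEUROG2, a neuronal transcription factor, and the neighbouring histone genes H2AC16 and H1-5, which share 1 peak. Of the genes with the highest percentiles in WT, MALL, TMEM37, STPG4 and EPB41L5 lie on chromosome 2 and CACNA1B on the far part of chromosome 9, and NEUROD1 and IL1A lie on chromosome 2 as well. These parts of the genome differ between the cell conditions as a whole. In the knockout these were SEMA3C, an axon guidance ligand, BDNF, a neurotrophin, TCIM, VSTM2B, PTHLH and FRMD1, besides uncharacterised loci. With gene windows of 3 kb 8 of the 26 named genes of this comparison kept their pattern, NEUROD1, IL1A, EPB41L5, DDX39B, NEUROG2, H2AC16 and H1-5 among them, while BRD7, H3C12, RPL29, MALL, TMEM37, STPG4, CACNA1B, SPARC, SEMA3C, BDNF, TCIM, VSTM2B, PTHLH and FRMD1 did not.

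MALL (chromosome 2, 110083870 to 110118139) stood at the 95.6 and 96.4 percentiles of the WT lists, and CACNA1B at 87.3 and 84.2. SEMA3C stood at 93.7 and 91.7 in the knockout lists, BDNF at 90.0 and 91.8, and SPARC at 51.6 and 66.8. Gene ends of WT alone numbered 205 and of the knockout alone 196, with sums of 401 against 280 and 258 for the other pairings. Regions numbered 5292 and 4730, and the sum of 10022 compares with 6967 and 6907. Regions on chromosome 2 contributed 1036 WT-only and 118 knockout-only, those on chromosome 9 contributed 438 and 123, and those on chromosome 17 contributed 140 and 492. Without these 3 chromosomes, an alternative chosen after seeing the data, the counts were 3678 and 3997, and the sum of 7675 compares with 5725 and 5728. With lists of equal length WT-only and knockout-only regions numbered 5686 and 3658, and without the 3 chromosomes 3956 and 3082. Of the olfactory receptors 3 of 365 (OR8U8, OR5AU1 and OR2C1) were called in the knockout alone, against 4.75% of other genes (Fisher's exact test, adjusted p = 0.00469). As these genes seldom carried a peak with either antibody, the result is not tied to the knockout. Peak numbers stood at a ratio of 1.07 (exact permutation p = 0.667, n = 2 each).

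Ends lost with anti-ARID1A in both YTHDF1-KO and siARID1A cells numbered 95, of the 205 and 754 lost in each among 13904 genes held by both WT libraries. Independent lists of these sizes would share 11.1. In a simulation all 6 anti-ARID1A libraries, WT included, were drawn at a single pooled rate per gene. There 52.2 were shared on average, with a range of 36 to 72 in 100 draws. Both simulated groups had the same expected loss, unlike the real 205 and 754, so these draws cannot judge the 95. The WT libraries cannot be split into groups of 2, so part of the excess over independent lists may come from the shared controls. Both conditions also had lower signal than WT on the far part of chromosome 9, where some of the shared genes lie, CACNA1B among them. In alternatives chosen after seeing the data 67 genes were shared without chromosomes 2, 9 and 17 and 55 with whole-gene windows, for which no simulation was made.

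The anti-YTHDF1 lists of siARID1A cells were compared with those of WT cells. Pairings that mix the 2 conditions gave nearly as many gene ends as the real pairing (831 and 854 against 869). The genes named below are therefore not shown to depend on ARID1A. Ends of JUN, ATF3 and BATF, of the AP-1 and ATF family of stress-responsive transcription factors, were called in both siARID1A and neither WT library. So were FOXA1, a lung lineage transcription factor, SFTPC, a surfactant gene of alveolar cells, AGER, CDKN1A, the p53-induced cell cycle inhibitor, SMARCC2, NKG7, RBFOX3 and the histone genes H2BC11 and H2AC11, and H3C2 and H2AC4, where each pair shares 1 peak. Called in both WT and neither siARID1A library were CCNA2, a cyclin of S phase, MCM3, the interferon-stimulated gene IFI6, RPS23 and DDX1. An end of ARID1A was called in both siARID1A and 1 of the 2 WT anti-YTHDF1 lists, and in neither YTHDF1-KO list. At the highest percentiles were CCDC12, KCNAB3, CEP170B and MALL in WT, and RAB37, SIX2, SMURF2, EPC2, OAT, NOG, AKR1E2 and ATL3 in siARID1A. Of these RAB37, SMURF2 and NOG, and RBFOX3, lie in the shifted part of chromosome 17. With gene windows of 3 kb 14 of the 36 named genes of this comparison kept their pattern, CCNA2, MCM3, DDX1, JUN, EPC2, OAT, NOG and the 4 histone genes among them, while ATF3, FOXA1, SFTPC, AGER, CDKN1A, SMARCC2, NKG7, RBFOX3, IFI6 and RPS23 did not. Nor did CCDC12, KCNAB3, CEP170B, MALL, RAB37, SIX2, SMURF2, AKR1E2 and ATL3.

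CCNA2 (chromosome 4, 121816444 to 121823883) stood at the 70.6 and 64.7 percentiles in WT. SFTPC stood at 81.1 and 86.8 in the siARID1A lists, FOXA1 at 77.0 and 65.8, SMURF2 at 92.5 and 88.6, and JUN at 0.754 and 81.8. Of 3 members of the AP-1 and ATF list held by neither WT library all 3 were called, against 7.16% of other genes (Fisher's exact test, adjusted p = 0.0156). Of the zinc finger genes 8 of 294 were called, less than the 7.35% of other genes (exact test, adjusted p = 0.0330), and of the olfactory receptors 0 of 375 (exact test, adjusted p = 1.38e-10). Olfactory receptors seldom carried a peak with either antibody, so few calls were likely in any pairing. With lists of equal length, an alternative chosen after seeing the data, the AP-1 and ATF list stood at an adjusted p of 1 and the zinc finger list at 0.0773, so those results no longer passed, while olfactory receptors stood at 8.71e-08. Of the lung epithelium genes 3 of 7 were called (exact test, adjusted p = 0.195).

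Gene ends called in siARID1A alone numbered 620, against 249 in WT alone, with sums of 869 against 831 and 854 for the other pairings. Regions numbered 3892 and 2203, with a sum of 6095 against 5923 and 6175. With lists of equal length siARID1A-only and WT-only regions numbered 2554 and 2211, a smaller excess. Pairings that mix the conditions were uneven as well, with 594 against 237 and 622 against 232 gene ends. At equal length they gave 2493 against 1749 and 2801 against 1545 regions. Peak numbers stood at a ratio of 1.21 (exact permutation p = 0.667, n = 2 each), a ratio that ranged from 1.01 to 1.44 when single lists were left out.

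The lists of both antibodies were set beside each other over all conditions. Ends of 71.1 ± 4.40% of protein-coding genes carried an anti-ARID1A peak, and of 44.8 ± 5.99% an anti-YTHDF1 peak (mean ± SD, n = 6 each). Of the 17116 genes tested 0 were called more often with either antibody (Fisher's exact test with Benjamini-Hochberg adjustment, lowest adjusted p = 0.0895), and 1604 had an unadjusted p under 0.05. At gene ends all 6 anti-ARID1A and no anti-YTHDF1 lists held 413 genes, among them DOCK6, SYDE1, SRI and RNF114, named after their values were seen. The cell cycle gene BUB1, the R-loop genes THOC1 and RNASEH2A, and SLC7A11 and AKR1C2 of the NRF2 list belong to this group. With lists of equal length 190 genes did, DOCK6, SYDE1 and SRI among them, but none of these members of the cell cycle, R-loop and NRF2 lists. With all peaks only USP17L25, which has near-identical copies, showed the opposite. Ends of 3707 genes were held by all 12 lists.

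Of the 21 gene lists 20 had a higher share of members with an anti-ARID1A peak, by exact permutation of 6 libraries against 6. Protein-coding genes as a whole stood at 71.1% against 44.8%. The lists were not tested against other genes here, so a pass does not set a list apart from them. Cell cycle genes stood at 98.6 ± 2.15% against 63.9 ± 9.74%, and R-loop resolution genes at 91.0 ± 7.18% against 56.3 ± 4.37%. Ribosomal proteins stood at 95.5% against 65.6%, NRF2 targets at 97.5% against 66.7%, N6-methyladenosine machinery at 95.8% against 61.7% and AP-1 and ATF genes at 99.0% against 79.2%. SWI/SNF subunits stood at 90.2% against 62.9%, p53 targets at 90.4% against 76.3%, DNA damage response genes at 84.0% against 61.1% and lung epithelium genes at 80.8% against 55.0%. Nucleic acid sensing stood at 78.3% against 51.7%, EMT at 73.3% against 40%, interferon-stimulated genes at 70.3% against 29.7%, and cytokines and chemokines at 64% against 30.7%. Neuronal markers stood at 68.3% against 45.8%, haematopoietic markers at 62.5% against 43.3%, immune checkpoint ligands at 61.5% against 37.5%, histones at 65.2% against 30.2%, zinc finger genes at 57.0% against 30.7% and olfactory receptors at 4.15% against 2.56%. Antigen presentation genes did not pass, at 44.8% against 38.5% (exact permutation p = 0.357). With lists of equal length 18 of 21 passed, all higher with anti-ARID1A, while antigen presentation, neuronal markers and olfactory receptors did not. Protein-coding genes as a whole then stood at 58.5% against 40.6%.

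As a share of peaks, gene ends took 18.8 ± 1.82% with anti-ARID1A and 19.9 ± 1.12% with anti-YTHDF1 (exact permutation p = 0.238, n = 6 each). With equal list lengths the order turned, to 30.4 ± 0.472% and 22.2 ± 2.23% (p = 0.00216 by exact permutation, the smallest these 924 assignments give). Cutting the lists matched the number of peaks but not their width.

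Most WT anti-YTHDF1 regions lay where anti-ARID1A was also called. Of 17304 regions held by both WT anti-YTHDF1 libraries 92.3% were held by both WT anti-ARID1A libraries, and 98.1% of those at gene ends, against 19.4% for shuffled positions, whose highest of 100 was 20.2%. Of all peaks of the single WT anti-YTHDF1 lists 70.7% and 69.1% were. The YTHDF1-KO anti-YTHDF1 lists, measured the same way, gave 89.8% of 15241 regions. In siARID1A cells 91.2% of 22071 anti-YTHDF1 regions were held by WT anti-ARID1A lists, and 76.7% by the anti-ARID1A lists of the same cells (68.7% away from gene ends). In the opposite direction 19.6% of WT anti-ARID1A regions were held by WT anti-YTHDF1 lists.

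The chromosomes differed in their share of peaks between the cell conditions. Chromosome 2 held 5.64 ± 0.529% of peaks in the 4 YTHDF1-KO libraries and 8.14 ± 0.529% in the 8 others, with no overlap (5.10 to 6.12% against 7.59 to 9.11%; exact permutation p = 0.00202, adjusted p = 0.0348 over 69 tests, the smallest these give). Chromosome 9 held 5.14 ± 0.172% in the 4 WT libraries and 3.86 ± 0.174% in the 8 others, again with no overlap (exact permutation, adjusted p = 0.0348). Of the 69 tests, which were chosen after the shares were seen, 17 passed, 5 for YTHDF1-KO, 2 for WT and 10 for siARID1A. Shares of a list add up to a fixed total, so these tests are not independent. The 4 libraries of a condition are 2 replicates with each of 2 antibodies, and they were permuted across antibodies. The p-values treat them as independent, so they describe these libraries and not further cell stocks. A pass can also rest on 1 antibody, as on chromosome 19 for siARID1A. There the anti-ARID1A shares were 8.12 and 7.47%, against 5.38 and 4.78% in WT. The anti-YTHDF1 shares were 7.80 and 8.21%, against 7.85 and 8.05% in WT. Chromosome 17 held 8.06 ± 1.54% in WT and 9.59 ± 1.52% in the others and did not pass (exact permutation, adjusted p = 0.0697). The authors' signal at regions called by all 4 libraries shifted by -0.53 in log2 of signal on chromosome 2 between YTHDF1-KO and WT with anti-ARID1A, and in 13 of 13 windows of 20 Mb. From 80 Mb on chromosome 9 the shift was -0.59, and before 60 Mb 0.03. From 40 Mb on chromosome 17 it was 0.52, and before that 0.05. In siARID1A cells the same ends of chromosomes 9 and 17 shifted by -0.58 and 0.54 with anti-ARID1A and by -0.58 and 0.40 with anti-YTHDF1, while chromosome 2 shifted by 0.10 and -0.09. The anti-ARID1A windows of siARID1A cells scattered widely, from -0.15 to 0.76 on chromosomes other than 2, 9 and 17, so the shift on chromosome 17 stands out less there. The segment bounds were chosen after the shifts were seen.

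**Figure D3:**
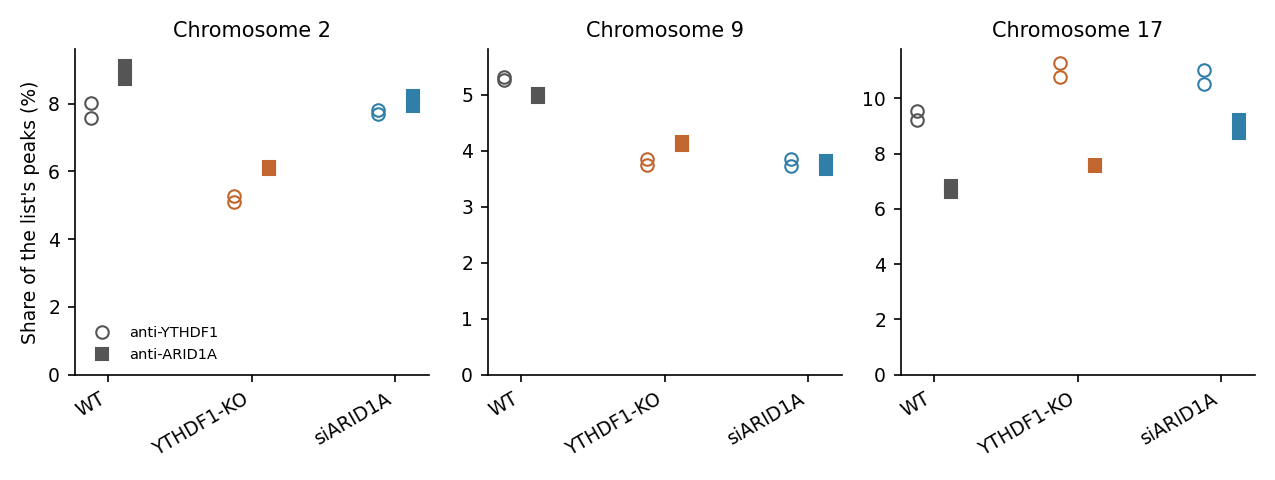
Percent of each list's peaks on chromosomes 2, 9 and 17, with a point per library, open circles for anti-YTHDF1 and filled squares for anti-ARID1A. On chromosome 2 the 4 YTHDF1-KO libraries lie between 5.10 and 6.12% and the 8 others between 7.59 and 9.11%.

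**Figure D4:**
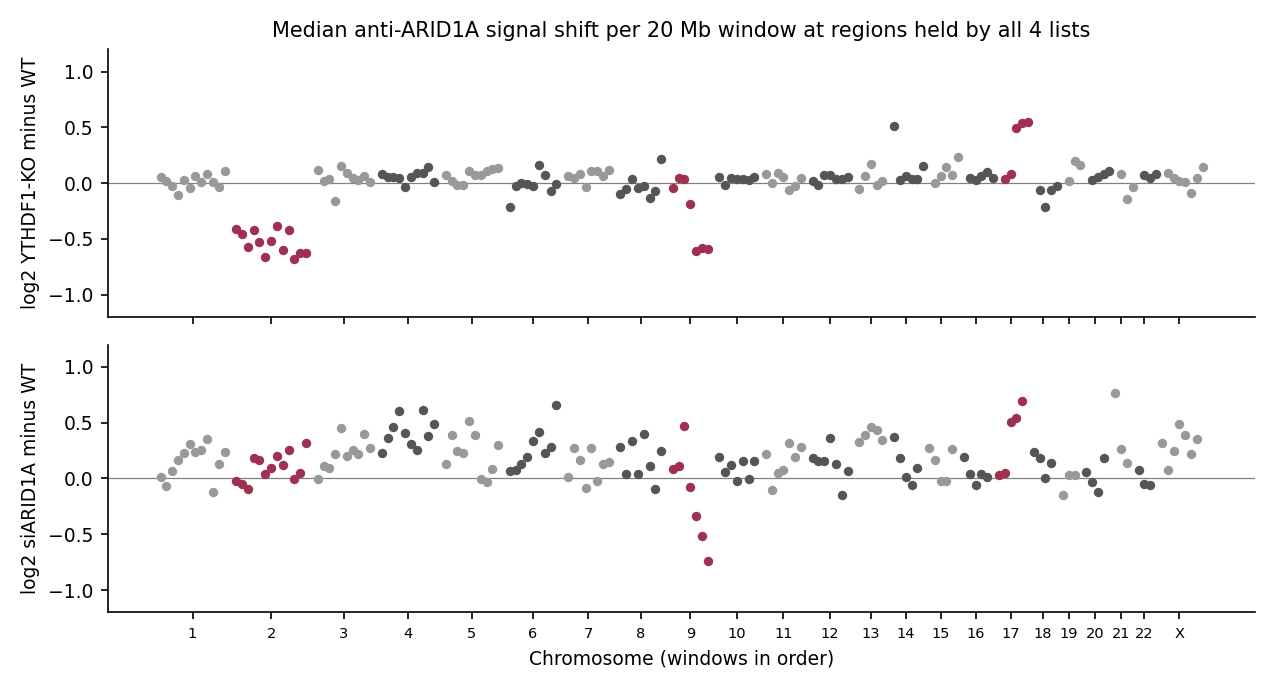
Median log2 difference of anti-ARID1A signal from WT per 20 Mb window along all chromosomes, for YTHDF1-KO cells (upper panel) and siARID1A cells (lower panel), each library centred on its own median, with chromosomes 2, 9 and 17 in red. On chromosome 2 all 13 windows of YTHDF1-KO cells lie below 0, and from 80 Mb on chromosome 9 all 3 windows do in both conditions.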

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

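Chosen only after the result was seen were the tests of list length for the anti-YTHDF1 lists and of copy number, single sites and batch for the chromosome-wide differences. So were the single lists, the weaker regions and the matched regions for the siARID1A lists.

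Between siARID1A and WT cells the antibodies went opposite ways in several measures, and these differences are the anti-ARID1A effect less the anti-YTHDF1 effect. The difference was -0.63 in log2 peak number, -1.39 in log2 covered length and -0.36 in log2 genes with a peak at an end, with exact permutation p of 0.111, 0.167 and 0.0556. It was 3.44 percentage points in the share of peaks at gene ends (exact permutation p = 0.111). In the share of listed signal on the mitochondrial chromosome it was 29.9 percentage points for siARID1A and 8.92 for YTHDF1-KO (exact permutation p of 0.167 and 0.111). The smallest p of these 36 assignments is 0.0556, above the threshold of 0.05 by design. The mitochondrial share ranged from 18.1% to 49.5% over the 12 lists. No single library was flagged in the 12 sets of 6 tested, where chance gives about 1 in 20. The test set the gap to the nearest library against the range of the set. Replicates that deviate together hide each other from it, so it cannot show that no condition stood apart. Both siARID1A anti-ARID1A lists had a higher mitochondrial share and a shorter covered length than every other anti-ARID1A list.

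The first pattern is the loss of anti-ARID1A regions in siARID1A cells, 15950 against 897 and at equal list length 9298 against 1335. Copy number differences do not account for it, since without chromosomes 2, 9 and 17 the ratio was 17.7, and at equal list length 6.97. A lower sensitivity of the siARID1A lists stays open beside loss of ARID1A binding by the knockdown. Of 5 groups of regions by WT signal, the one with the highest was taken. There the share missed by both lists away from gene ends exceeded that at gene ends by 0.942 points, less than the 2.77 points between the libraries. This comparison cannot decide, since only 1.05% were missed by both lists away from gene ends, while the 2.77 points come from single lists. The single lists, compared after this result was seen, missed 5.59% and 2.82% away from gene ends, against 1.08% and 0.497% at gene ends. Among weaker regions gene ends were missed less, 24.4% against 48.6% in group 2 from the bottom, where the libraries differed by 11 and 7.99 points, and so were gene ends matched with other regions on total and highest signal (8.39% against 18.3%), which goes against an even loss. The YTHDF1-KO lists, without the knockdown, showed this contrast at a smaller size in points (6.45% against 16.2% in group 2, 2.10% against 5.41% when matched), so it may reflect the kind of region and was not taken to decide.

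The second pattern is that anti-YTHDF1 lists of YTHDF1-KO cells resemble those of WT cells. Signal that does not need YTHDF1 may account for much of it: of regions in both knockout lists 58.9% were held by both WT lists, where the highest of 100 shuffles gave 6.34%, and 89.8% were held by WT anti-ARID1A. The list length of WT was not separated, since at equal length the real pairing gave 1.10 times the regions of the larger other pairing. Copy number was not decided either: without chromosomes 2, 9 and 17 the ratio of WT-only to knockout-only regions at equal length was 1.46, but the pairings that mix the cell stocks gave 1.51 and 1.76, and the ratio does not measure how alike the lists are. YTHDF1 binding that remains in the knockout, and whether the knockout removed the protein, were not tested.

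The third pattern is the shift of chromosome 2 and of parts of 9 and 17 between the cell conditions. Copy number differences between cell stocks are a candidate explanation, as 100% of the 13 windows of chromosome 2 had a lower anti-ARID1A signal in YTHDF1-KO and 8 of 8 a lower anti-YTHDF1 signal, with shifts of -0.53 and -0.36 where log2 of 2/3 is -0.58. The same 100% argues against YTHDF1 acting on ARID1A at single sites, and a batch that crosses cell stocks is argued against by the gap of 1.47 points between the chromosome 2 shares of the knockout and other libraries. A batch shared by all libraries of a stock cannot be told apart from the stock. The shifts of chromosomes 9 and 17 in siARID1A cells as well as in YTHDF1-KO cells place WT apart from both.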

How the results depend on the processing

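Chosen after seeing the data were the top 20000 peaks, the omission of chromosomes 2, 9 and 17, whole-gene windows and the gene lists with 3 kb windows. Each count or ratio was judged by its own size, and the difference in gene-end share also by its sign and test. Of 257 alternative values 156 stayed near the reported value and 98 moved. Of the gene-end shares 1 kept its direction and passed a threshold that it had missed. Another 2 turned direction, and of these the share at equal list length passed the threshold as well. This tally does not score which of a pair of counts was larger, a ratio crossing 1, or the tests of single gene lists. Such turns occurred: without chromosomes 2, 9 and 17 anti-ARID1A regions of WT and YTHDF1-KO alone were 3678 and 3997, and by covered length the YTHDF1-KO ratio was 0.894 with anti-YTHDF1. At equal list length the anti-ARID1A regions without these chromosomes were 3956 and 3082 and did not turn. The AP-1 and ATF and the zinc finger list no longer passed with 3 kb windows (adjusted p of 0.224 and 0.255 by Fisher's exact test) or at equal length, nor the zinc finger list without chromosomes 2, 9 and 17 (0.0537). The cause was not tested except where the construction shows it. The motif comparison and its alternatives were not run. Depth is unknown, so what it limits cannot be stated.

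Counts of regions follow the number and size of units. In the upper 50% of each list WT-only and other-only regions were 1941 and 1147 for anti-YTHDF1 in YTHDF1-KO, 8563 and 387 for anti-ARID1A in siARID1A, 2566 and 2212 for anti-ARID1A in YTHDF1-KO, and 1103 and 2161 for anti-YTHDF1 in siARID1A. With the top 20000 peaks they were, in the same order, 1672 and 1017, 2765 and 682, 1388 and 808, and 1128 and 1334. In 1 kb bins they were 11045 and 6243, 73273 and 2354, 22678 and 17688, and 6857 and 11510. At equal list length anti-ARID1A WT-only regions against siARID1A were 9298 and siARID1A-only gene ends 140, and anti-YTHDF1 siARID1A-only regions 2554. By covered length the ratio was 0.456 for anti-ARID1A in siARID1A and 0.964 in YTHDF1-KO.

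The share of peaks at gene ends, anti-ARID1A less anti-YTHDF1, was -3.17 points with 3 kb windows (exact permutation p = 0.0455), 8.17 at equal list length (exact permutation p = 0.00216) and 1.77 in the upper 50% (exact permutation p = 0.165), against -1.09 as reported. Co-occupancy was 90.5% with an overlap of 50%, the shared loss 55 genes with whole-gene windows, and 3 gene list tests passed with 3 kb windows against 6, of which 5 are described. Of 127 named gene patterns 45 held with 3 kb windows, 95 with 500 bp, 104 at equal length and 78 in the upper 50%.

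Leaving out single libraries raises the counts by construction, since fewer lists must meet the pattern. For anti-YTHDF1 in YTHDF1-KO cells WT-only regions ran from 6176 to 28820, other-only regions 3142 to 24876, gene ends 1352 to 2082 and 473 to 1156, and peak ratios 0.839 to 1.19. For anti-ARID1A in siARID1A cells WT-only regions ran from 21398 to 45432, other-only regions 1696 to 12665, gene ends 1078 to 1831 and 143 to 319, and peak ratios 0.739 to 0.821. For anti-ARID1A in YTHDF1-KO cells WT-only regions ran from 10096 to 23386, other-only regions 7874 to 25406, gene ends 403 to 584 and 427 to 576, and peak ratios 1.03 to 1.12. For anti-YTHDF1 in siARID1A cells WT-only regions ran from 4028 to 23977, other-only regions 5424 to 28447, gene ends 670 to 1070 and 1041 to 2187, and peak ratios 1.01 to 1.44. Co-occupancy ran from 69.1 to 94.8%, the shared loss from 121 to 315 genes, and the difference in gene-end share from -1.64 to -0.711 points, with 0 genes called between the antibodies in each.

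With a replicate block (exact sign-flip test over 6 pairs) 0 genes were called more often with anti-ARID1A and 0 with anti-YTHDF1, with 414 at an unadjusted p under 0.05, and the share at gene ends gave -1.09 (exact p = 0.156). The differences between replicates 2 and 1 of each group correlated at -0.0099 to 0.014 over 15 pairs of groups, none above 0.1, so the numbers do not pair the libraries.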

Other observations

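The gene classes and equal-length lists here were chosen after seeing the data, as was the test of genes held by all libraries of one antibody and none of the other; the test of list length was not.

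All 6 gene classes examined, small RNA genes among them, were held more often by anti-ARID1A lists when all lists had equal length. Cutting the lists did not match the width of their peaks. A gene counted as held if a peak overlapped any part of it or the 1 kb to either side, so these shares are not those at gene ends. Of 443 tRNA genes, transcribed by RNA polymerase III, anti-ARID1A lists held 55.3 ± 1.24% and anti-YTHDF1 lists 35.4 ± 4.82% (mean ± SD, n = 6 each; exact permutation, adjusted p = 0.00260). The anti-YTHDF1 share of tRNA genes was 35.9% and 35.2% in WT, 29.3% and 30.5% in YTHDF1-KO and 40.2% and 41.1% in siARID1A cells. Both YTHDF1-KO lists also lay below both WT lists for protein-coding genes (54.9% and 54.9% against 55.7% and 57.4%), lncRNAs, snoRNAs and miRNAs. For snRNAs they lay between the WT values. A lower share in the knockout was thus not particular to tRNA genes. Genes of snRNAs stood at 55.4% against 43.7%, snoRNAs at 15.4% against 9.48%, miRNAs at 31.3% against 23.2%, lncRNAs at 31.3% against 24.8% and protein-coding genes at 66.4% against 56.3%. All 6 classes passed at an adjusted p of 0.00433 or less by exact permutation, so the difference was not particular to small RNA genes. Median widths before cutting were 1701 and 1754 bp in WT anti-ARID1A lists and 1262 and 1057 bp in WT anti-YTHDF1 lists. In siARID1A anti-ARID1A lists they were 1104 and 1243 bp. There miRNA shares were 25.59% and 27.68%, against 26.64% and 22.03% in WT anti-YTHDF1 lists. In the other classes both stayed above every anti-YTHDF1 list. The part played by width was not tested. Members of multicopy classes such as tRNA and snRNA genes have near-identical copies, so their assignment is uncertain.

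Genes held by all 6 anti-ARID1A and no anti-YTHDF1 lists, or the reverse, numbered 414. In 100 of the 462 ways to divide the 12 libraries 1, the real division, gave as many, and the highest other gave 50. This measure was taken up after 0 genes passed the planned test. The real division also separates the longer anti-ARID1A lists (71271 to 106882 peaks) from the shorter anti-YTHDF1 lists (40562 to 59632). The splits therefore do not tell the antibody from list length. For genes past the threshold the real division gave 0 and so did each of the others, so 100 of 100 gave as many; no count lies below 0, so this says nothing about chance. Whether the longer anti-ARID1A lists account for the difference was not decided by the planned count, as 0 genes passed at equal length in either direction, with 867 at an unadjusted p under 0.05. The 190 genes against 2 (NPIPB5 and USP17L25, both with near-identical copies) at equal length are a substitute taken up after that, with peak width not matched.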
